A study of Mus musculus with 6 samples.

How the data were processed

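Total RNA of 6 samples of mouse embryonic stem cells, 3 of a Trpm7 knockout clone and 3 of a wild-type clone, was biotin-labelled and hybridised to Illumina bead arrays, per the labels. Signal intensity and a detection p-value for each of 45281 probes were deposited by the authors for each array. They came from GenomeStudio, per the submitters' processing notes, whose version is not given in the sources used here. The deposited intensities had a linear scale and were neither background-corrected nor normalized between arrays, as the values showed. The authors' value table in the series matrix held intensity minus 1 constant per array (48.6 to 54.2; the same for all probes within 0.012), with column medians of 4.08 to 5.22 and no centring of genes. It was used as an alternative.

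Values were background-corrected, quantile-normalized and put on the log2 scale with neqc in limma 3.58.1 (R 4.3.3), with an offset of 16 and with the negative controls' mean and SD inferred from the deposited detection p-values. A fold change on this scale understates the change of dim genes. A probe was kept where its detection p was under 0.05 on all 3 arrays of at least 1 genotype, which left 19123. Probe annotation gave 1 symbol for 34885 probes, several for 18 and none for 10378. Of the probes with 1 symbol, 34807 were found by gene identifier in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols and gave the chromosomes. Older symbols were mapped by hand for 18 list members. Of the kept probes, 16589 had 1 symbol, 2527 none and 7 several. A gene was represented by its kept probe with the highest mean, which gave 10692 genes, 4014 of them with several kept probes.

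The genotypes were compared with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p under 0.05. Where a gene was not above background on any array of a genotype, the difference was given as "at least", from the brighter group's mean against, per array, the higher of the lowest signal among detected probes and the gene's own. Gene lists (39, fixed before the data were examined) and chromosomes were tested with camera at a preset correlation of 0.01, for lists of at least 5 and chromosomes of at least 20 tested genes. Camera with an estimated correlation and fry were run beside it. The former takes its degrees of freedom from the arrays and not from the genes, and so has little power with 6 arrays. A list's mean relative to all genes is the mean log2 change of its tested members minus that over all genes tested. Counts "adjusted over the list alone" use p-values adjusted among a list's members. The interval of a chromosome's median came from 2000 bootstrap samples of its genes, which are not independent replicates.

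Apart from the exceptions below, the genes named were set by a rule fixed before the data were examined. They are Trpm7, the 10 with the largest rise and the 10 with the largest fall among genes past the threshold, with groups that did not overlap and detection on all arrays of the higher group, skipping names of clones and gene models; up to 4 members per list past the threshold with the largest change; and 12 genes of pluripotency, magnesium transport and metallothioneins. Col1a1, Col1a2, Col3a1, Postn, Lum, Ccn2, Eif2s3x, Xist, the other Y-linked genes and probes, and the 12 genes drawn array by array were chosen after their values were seen.

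On simulated data for this comparison (10692 genes, 200 changed), the steps recovered 88.1% of 67 genes changed 1.5-fold, 100% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 16 false calls. A further list of 20 genes was lowered 1.5-fold and passed camera. Of 200 unchanged lists, 0 passed. Genes were simulated independently on the normalized scale. Correlation among list members, background correction, normalization and the detection filter were thus not tested, and the result does not bear on false list calls in the real data. No arrays were duplicates. Alternatives were other background corrections (none, or normexp with an offset of 50), median scaling, the series matrix values, no detection filter or detection p under 0.01 on all 6 arrays, the mean of a gene's probes, trended and robust moderation, array weights, the replicate number as a block, and leaving out each array. Leaving out X and Y genes was added after the data were seen. Figures were drawn with matplotlib 3.10.9.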

Results

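Gene expression was measured in mouse embryonic stem cells of C57BL/6 background that lacked Trpm7, an ion channel fused to a protein kinase that conducts magnesium, calcium and zinc, and in wild-type cells. Each genotype was represented by 1 clone with 3 samples, and each sample was hybridised to 1 bead array. The cells had been kept on irradiated fibroblast feeders in medium with added magnesium, and were then passaged 3 times on gelatin without feeders. The arrays carried 45281 probes, of which 19325 to 20307 per array were above background at a detection p under 0.05. The median raw signal was 58.4 ± 0.955 (SD, n = 3) in the knockout and 54.7 ± 2.09 (SD, n = 3) in the wild type. Across probes of a pair of arrays, values correlated at 0.991 to 0.996 within a genotype and at 0.971 to 0.979 between genotypes. The labels do not say that the 3 samples of a clone were separate cultures, so p-values measure only the spread between these samples, which may be technical. Since each genotype is 1 clone, a difference between genotypes is also a difference between clones. The number of arrays limits the precision.

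Trpm7 itself could not serve as a check of the labels. Its 3 probes lay near background on the arrays of both genotypes and none passed the detection filter. The brightest had a normalized log2 intensity of 4.53 ± 0.17 (SD, n = 3) in the knockout and 4.69 ± 0.08 (SD, n = 3) in the wild type, and was detected on 1 and 2 arrays, respectively. The log2 change of -0.16 ± 0.09 (SE) did not pass the test (limma adjusted p = 0.437 over all probes; two-sided exact permutation p = 0.2, where 0.1 is the smallest that 3 against 3 arrays can give). Where the probes lie relative to the deleted part is not given in the sources used here.

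The clones differed in a large part of the transcriptome, mostly by small amounts. Of 10692 genes tested, 3745 (35.03%) passed an adjusted p under 0.05 in limma, 1868 higher and 1877 lower in the knockout. Of these, 378 changed at least 2-fold, 130 higher and 248 lower. Groups did not overlap for 5145 genes (48.1%), against 10% expected for a gene if the arrays were interchangeable. Genes share the same arrays and are not independent, so the excess is no test of chance. The count of at least 2-fold changes depends on the background correction, and was 174 without one and 158 with normexp at an offset of 50.

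**Figure D1:**
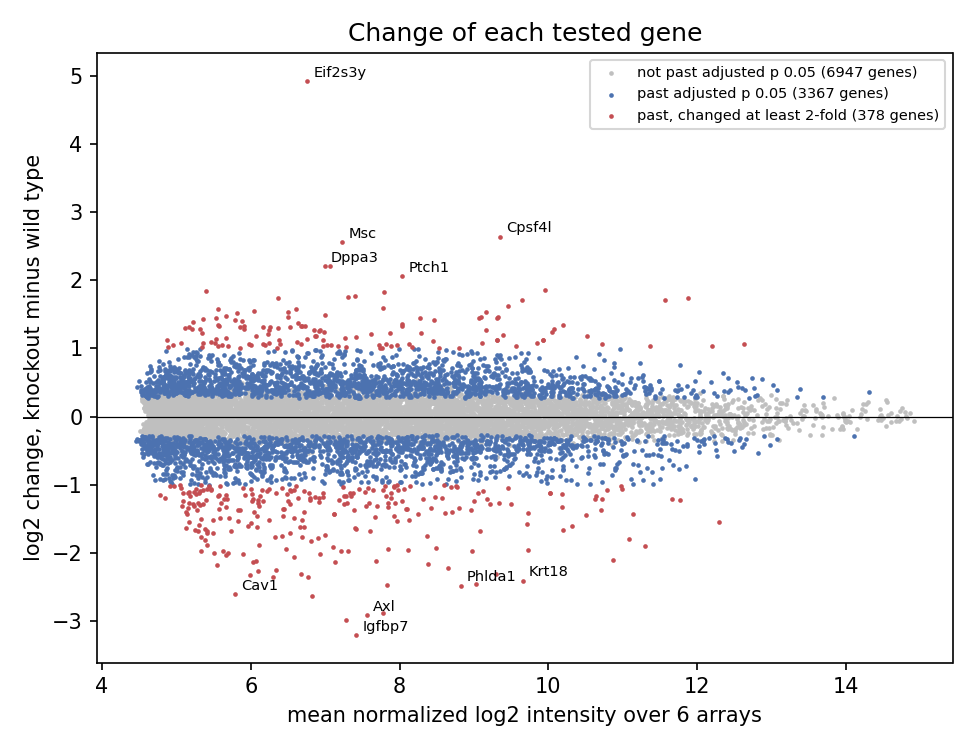
Log2 change of each tested gene (knockout minus wild type) against its mean normalized log2 intensity over the 6 arrays, 1 point per gene. The 378 genes in red passed the test and changed at least 2-fold, and 248 of them lie below 0.

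Among the genes with the largest rise, Eif2s3y, a Y-linked translation initiation factor subunit, was at least 24.9-fold higher in the knockout, as it was below background on the wild-type arrays (adjusted p = 1.8e-08). Dppa3 (Stella), a maternal and germ cell factor, rose 4.61-fold (log2 change 2.21 ± 0.15 SE, adjusted p = 1.0e-06), and Khdc3, of the oocyte subcortical maternal complex, rose 3.41-fold. Msc, a basic helix-loop-helix repressor, rose 5.90-fold, and Ptch1, the hedgehog receptor, rose 4.17-fold. The rise was 6.23-fold for Cpsf4l, 4.64-fold for Ms4a10, 3.61-fold for the thyrotropin-releasing hormone gene Trh, 3.59-fold for the ryanodine receptor gene Ryr3 and 3.56-fold for the pro-apoptotic gene Pmaip1.

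Among the genes with the largest fall, Igfbp7, a secreted growth factor binding protein, was 9.20-fold lower in the knockout (log2 change -3.20 ± 0.12 SE, adjusted p = 2.0e-08). The receptor tyrosine kinase gene Axl was 7.51-fold lower, the caveolin gene Cav1 6.07-fold, Phlda1 5.57-fold, the keratin gene Krt18 5.29-fold, and the proteoglycan gene Bgn 4.96-fold. Cav1 was detected on only 1 knockout array, so the size of its fall is uncertain. Pramel39 and Pramel37 were 7.94-fold and 7.35-fold lower and Tcstv3 5.09-fold lower. These last 3 belong to multigene families whose probes may read several members, so which member changed is uncertain. Tnfrsf22 was 5.50-fold lower by its brightest probe, while its other 3 probes had small positive log2 changes that did not pass (0.09 to 0.23), so its direction is uncertain.

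Core pluripotency transcripts were present at high level in both clones. Pou5f1 (Oct4) had a log2 intensity of 12.5 ± 0.06 (SD, n = 3) in the knockout and 12.7 ± 0.009 (SD, n = 3) in the wild type, with a log2 change of -0.15 ± 0.10 (SE, adjusted p = 0.251). The changes of Sox2 (0.04 ± 0.14 SE) and Zfp42 (-0.03 ± 0.10 SE) did not pass either (adjusted p = 0.86 and 0.826). Nanog was 1.35-fold lower (adjusted p = 0.031), a call that was lost with median scaling (adjusted p = 0.119), with no detection filter (adjusted p = 0.0824) and without knockout replicate 2 or 3 or wild-type replicate 1 or 3 (adjusted p = 0.081, 0.108, 0.128 and 0.0651), and its other probe did not pass (-0.21). Klf4 had a log2 change of 0.31 ± 0.14 (SE, adjusted p = 0.113) by its brightest probe, and its other 2 probes passed as higher (0.57 and 0.44). In the naive pluripotency list, 5 of 23 tested members rose and 2 fell, with a median log2 change of 0.02. Dppa3, Gbx2 (0.55) and Sall4 (0.52) rose. Jam2 fell by its brightest probe (-0.77) and by 2 others (-0.71 and -1.34), while the remaining 3 did not pass (-0.06, 0.07 and 0.08), so its fall is uncertain. In the core pluripotency list 4 of 14 rose, Lefty1 (1.71), Lin28a (0.60), Gdf3 (0.52) and Sall4, and 1 fell. Another probe of Sall4 (0.28) and of Lin28a (0.09) did not pass. In the formative and primed epiblast list 6 of 16 rose, among them Fgf8 (1.43), Lef1 (1.39) and Sall2 (0.76), and 1, Cldn6 (-0.99), fell. None of these 3 lists passed the set test (adjusted p = 0.562, 0.562 and 0.134).

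**Figure D2:**
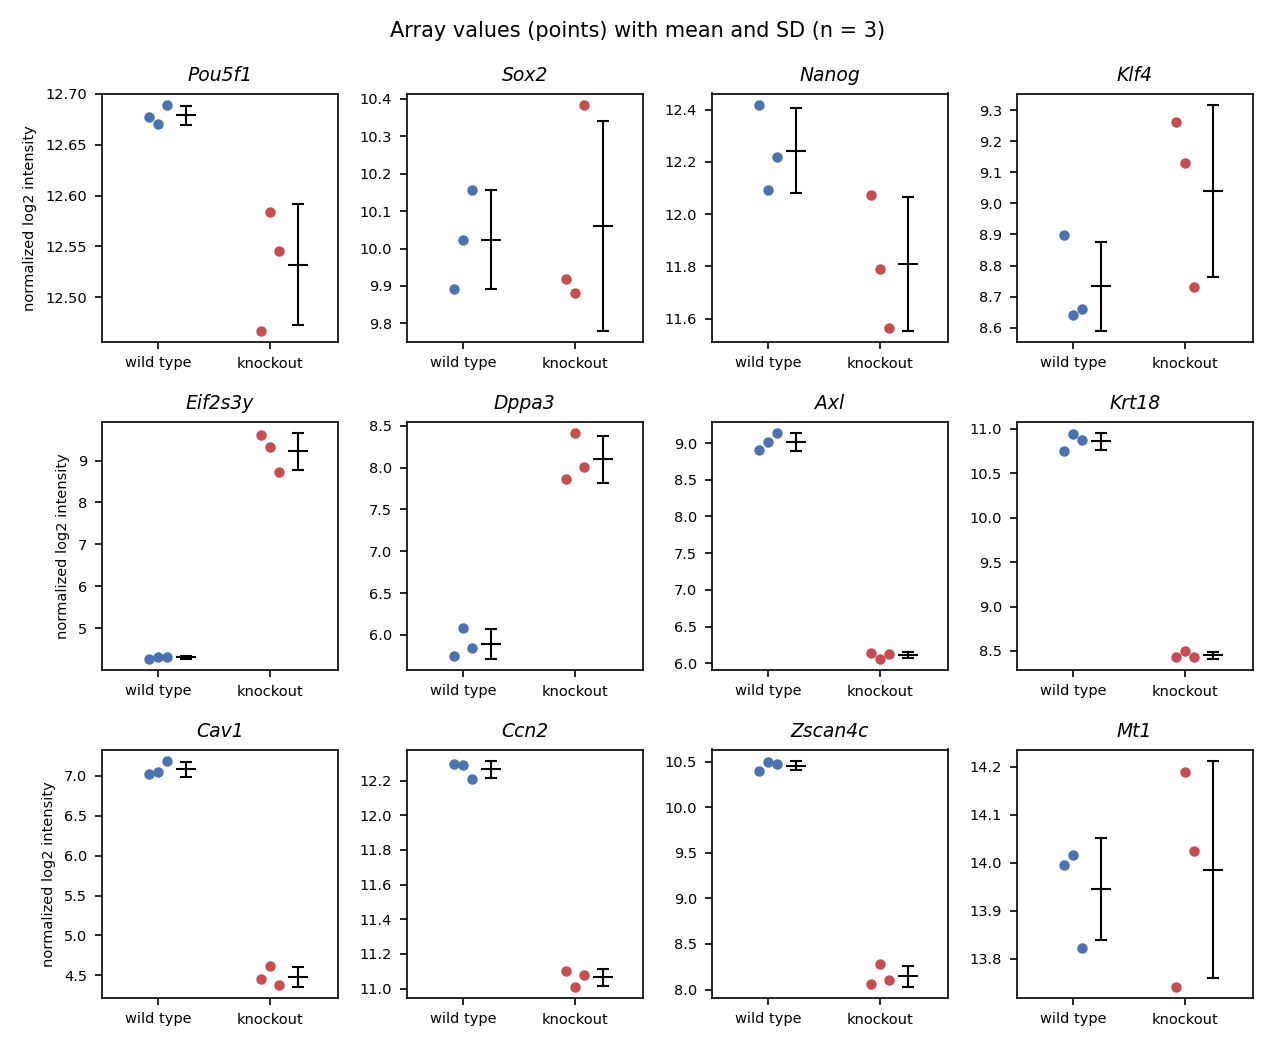
Normalized log2 intensity of 12 genes on each array (points), with mean and SD over the 3 arrays of each clone (bars); each panel has its own axis. Pou5f1 and Sox2 differed by 0.15 or less between clones. Axl, Krt18, Cav1, Ccn2 and Zscan4c were lower and Dppa3 and Eif2s3y higher on every knockout array than on any wild-type array. Pou5f1 and Nanog were also lower on every knockout array, by small amounts.

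Transcripts of the 2-cell-like state, a rare embryonic state within stem cell cultures, were lower in the knockout, while more germline genes rose than fell. Of 12 tested members of the 2-cell-like list, 10 fell and 0 rose (10 and 0 when adjusted over the list alone), with a median log2 change of -1.55. Zscan4c was 4.95-fold lower, Gm428 3.77-fold and Tdpoz4 3.50-fold. Zscan4c and Tdpoz4 belong to multigene families whose probes may read several members, so which member changed is uncertain. Tdpoz4 was detected on only 1 knockout array, so the size of its fall is uncertain. The list passed camera (adjusted p = 1.3e-09), but not with an estimated correlation (adjusted p = 0.0987). Its mean log2 change relative to all genes was -1.37, and -0.91 without background correction or -0.85 with normexp at an offset of 50. In the germline list 11 of 16 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.49. Besides Dppa3, Tuba3a rose 2.67-fold and the X-linked homeobox genes Rhox9 and Rhox6 rose 2.33-fold and 2.27-fold. The Tuba3a probes may also read Tuba3b. Camera gave an adjusted p of 2.5e-05, and an adjusted p of 0.0987 with an estimated correlation. The mean relative to all genes went from 0.66 to 0.41 with no detection filter.

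More genes of the actomyosin and fibroblast lists fell than rose. In the list of actomyosin and focal adhesion genes, 20 of 31 fell and 0 rose (20 and 0 adjusted over the list alone), with a median log2 change of -0.45. The annexin genes Anxa1 and Anxa2 were 3.99-fold and 3.72-fold lower, Tagln (transgelin) 3.36-fold and the calpain gene Capn2 3.11-fold (another Capn2 probe, at 0.23, did not pass). Anxa1 was detected on only 1 knockout array, so the size of its fall is uncertain. In the list of fibroblast genes, which marks feeder cells, 19 of 25 fell and 1 rose (19 and 2 adjusted over the list alone), with a median of -0.76. Ccn1 was 3.92-fold lower, Lox (lysyl oxidase) 3.91-fold (detected on only 1 knockout array) and Lgals1 (galectin) 3.03-fold, while Dcn (decorin) was 1.76-fold higher. The leading fibroblast collagens were near background, with Col1a1 detected on 3 wild-type arrays and 0 knockout arrays, Col1a2 on 0 and 1, and Col3a1 on 0 arrays. In the epithelial-mesenchymal list 17 of 25 fell and 2 rose (17 and 3 adjusted over the list alone; median -0.54). Its members with the largest fall were mostly epithelial, with Krt8 4.31-fold, Krt18 5.29-fold and Krt19 2.76-fold lower beside Tgfb2, 2.87-fold lower. The 3 lists share up to 4 tested members. Each passed camera (adjusted p = 5.3e-08, 1.2e-09 and 1.6e-05), but not with an estimated correlation (adjusted p = 0.0987, 0.0677 and 0.0987).

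Among lineage lists, primitive and definitive endoderm passed, with 9 of 23 tested members lower and 3 higher (10 and 3 adjusted over the list alone; median -0.30). The basement membrane collagens Col4a1 and Col4a2 were 3.20-fold and 2.85-fold lower, beside Krt8 and Krt18 (camera adjusted p = 0.00262; adjusted p = 0.28 with an estimated correlation). Of 39 HOX genes listed 12 were tested, of which 9 fell and 0 rose (10 and 0 adjusted over the list alone), all from low signal. Hoxd8 was at least 1.36-fold and Hoxa5 at least 1.28-fold higher in the wild type. The list's median was -0.38, or -0.31 with the 5 genes not above background in the knockout at their bound (camera adjusted p = 0.00136; adjusted p = 0.0987 with an estimated correlation). Its mean relative to all genes was -0.37, and depended on how low signal was treated and on knockout replicate 3. It was -0.12 with no detection filter, -0.19 without background correction, -0.17 with normexp at an offset of 50, and -0.22 without that replicate. With detection on all arrays too few members were left to test. The neural, mesoderm and trophectoderm lists did not pass (adjusted p = 0.693, 0.407 and 0.382). Their members went both ways, with 3 higher and 4 lower of 9, 3 and 4 of 17, and 5 and 9 of 18. Nes (nestin) was 2.11-fold lower and Fgfr2 2.73-fold higher.

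In the list of CDK inhibitors and quiescence genes, 8 of 18 fell and 1 rose (10 and 1 adjusted over the list alone). Ccng2 was 4.51-fold lower, the CDK inhibitor gene Cdkn2b 2.47-fold and Ccnd2 2.28-fold. Ccng2 was detected on 1 knockout array and Cdkn2b on 2, so the size of their falls is uncertain. Ccnd2 is a cyclin that promotes the cell cycle. In the ribosome biogenesis list 11 of 23 rose and 1 fell (12 and 1 adjusted over the list alone), among them Pes1 (1.81-fold) and Srm (log2 change 0.59). In the unfolded protein response list 7 of 20 rose and 0 fell (7 and 0 adjusted over the list alone), with the chaperone gene Hyou1 2.00-fold and Pdia4 1.61-fold higher. Of 32 amino acid stress genes, 10 fell and 0 rose (10 and 0 adjusted over the list alone), led by Atf5 (3.36-fold) and Nupr1 (2.58-fold). Of 25 p53 targets 13 fell and 3 rose (16 and 4 adjusted over the list alone), with Polk 2.51-fold lower and Pmaip1 higher. Of 17 genes of FGF and ERK feedback 8 fell and 2 rose (8 and 3 adjusted over the list alone), with Phlda1 and Ier3 (2.65-fold) lower. Of 21 interferon-stimulated genes 12 rose and 4 fell (13 and 5 adjusted over the list alone), with Oasl2 3.32-fold and Irf1 2.53-fold higher and B2m 2.99-fold lower. In this order the lists gave camera adjusted p = 0.000862, 0.00764, 0.00764, 0.00275, 0.00871, 0.0331 and 0.0262. With an estimated correlation none passed (adjusted p = 0.0987, 0.259, 0.612, 0.67, 0.664, 0.67 and 0.67). The amino acid stress call was lost without knockout replicate 2 (adjusted p = 0.084; mean relative to all genes -0.35 before and -0.20 after), the FGF call without knockout replicate 1 (adjusted p = 0.106), and the interferon call without knockout replicate 2 (adjusted p = 0.0676), with no detection filter (adjusted p = 0.0506), with detection on all arrays (adjusted p = 0.0722) and with the mean of probes (adjusted p = 0.0784).

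**Figure D3:**
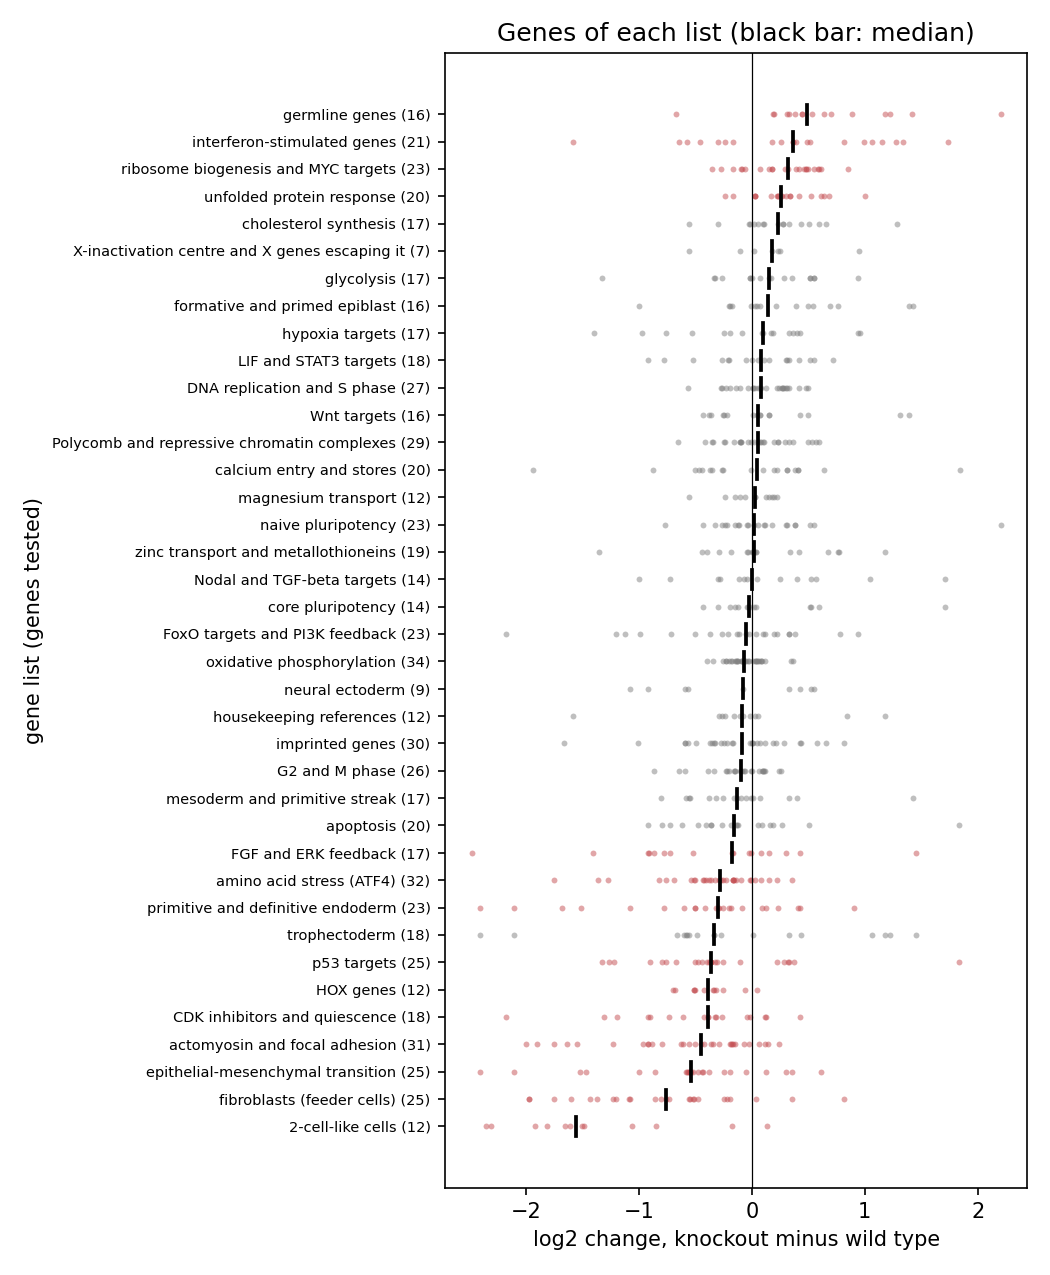
Log2 change (knockout minus wild type) of each tested gene (points) in the 38 lists tested, with the list's median as a black bar and the number of tested genes in brackets. The 14 lists in red passed camera at an adjusted p under 0.05; none of them did with an estimated correlation.

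In all, 14 of 38 lists passed camera at its preset correlation, 4 higher and 10 lower in the knockout. With an estimated correlation 0 passed (lowest adjusted p = 0.0677), and fry, which tests a list without comparing it with other genes, gave 22. The estimate also ties camera's degrees of freedom to the 6 arrays, which leaves little power over 38 lists. For the fibroblast list it was -0.024, below the preset 0.01, yet the unadjusted camera p went from 3.2e-11 to 0.00178. Failing this version thus does not show that correlation among members accounts for a call. The 10 ways of splitting the 6 arrays into 3 and 3 gave at most 14 lists apart from the real one. The other splits keep part of the clone difference, so list calls can carry over into them. The number of lists past camera therefore neither sets the genotype split apart nor argues against its lists. The FGF list's median of -0.17 was matched or exceeded in size in 4 of the 9 other splits, and the endoderm list's -0.30 was nearly matched (0.296).

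The lists of transport genes for the ions that Trpm7 conducts did not pass camera, which tests for a shift in 1 direction. Changes that go both ways within a list can escape it. Of all genes tested, 35.03% passed singly. Of 12 tested magnesium transport genes only Mmgt2 passed (1.47-fold lower), and the list had a median log2 change of 0.03, a mean of -0.01 and a test direction of higher (camera adjusted p = 0.983). Trpm6, Slc41a1, Slc41a2, Magt1 and Cnnm4 were not tested, since their probes did not pass the detection filter. Of 19 zinc genes 5 rose and 2 fell, with the zinc exporter gene Slc30a1 2.26-fold higher and Slc30a3 2.55-fold lower (camera adjusted p = 0.601). The metal-responsive factor gene Mtf1 was 1.70-fold higher by its brightest probe. Its other 2 probes did not pass (-0.04 and -0.06), and the call was lost with the mean of probes (adjusted p = 0.0803). The metallothionein genes Mt1 and Mt2 did not pass, with log2 changes of 0.04 ± 0.13 and 0.34 ± 0.15 (SE; adjusted p = 0.831 and 0.0984). Of 20 calcium genes 6 rose and 7 fell, with Ryr3 higher and S100a6 (3.82-fold) and the store-operated channel gene Orai1 (1.83-fold) lower (camera adjusted p = 0.949; median 0.04, mean -0.03 and test direction lower).

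The cell cycle lists did not pass, with 4 higher and 1 lower of 27 S phase genes and 0 higher and 3 lower of 26 G2 and M phase genes (camera adjusted p = 0.299 and 0.401). Of 34 oxidative phosphorylation genes 1 passed, Ndufa2, 1.32-fold lower, a call lost with median scaling (adjusted p = 0.111; list adjusted p = 0.5). Glycolysis (6 higher and 3 lower of 17), hypoxia (5 and 4 of 17) and cholesterol synthesis (5 and 1 of 17) gave adjusted p = 0.5, 0.85 and 0.134. Eno2 was 2.51-fold and Bhlhe40 2.63-fold lower, and Fdps 2.44-fold higher. FoxO targets (4 higher and 6 lower of 23), Wnt targets (3 and 1 of 16), Nodal targets (5 and 2 of 14) and STAT3 targets (4 and 3 of 18) gave adjusted p = 0.465, 0.562, 0.5 and 0.708. Irs2 was 2.29-fold lower, and Notum and Tgfbi were 2.48-fold and 2.07-fold higher. Igf1r was 2.17-fold lower by its brightest probe, while its other 2 did not pass (-0.17 and -0.22). Polycomb genes (7 higher and 2 lower of 29), imprinted genes (5 and 10 of 30), apoptosis genes (2 and 8 of 20) and housekeeping references (2 and 2 of 12) gave adjusted p = 0.562, 0.461, 0.25 and 0.585. The imprinted gene Grb10 was 3.16-fold lower, Bcl2 1.89-fold lower and the transferrin receptor gene Tfrc 2.27-fold higher. Of 7 X genes that escape inactivation or lie in its centre 1 passed, Mid1, 1.93-fold higher (list adjusted p = 0.465). Median, mean and test differed in sign also for the core pluripotency list (-0.03, 0.15, higher) and the hypoxia list (0.10, -0.01, higher).

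The Y-linked list had 3 tested members, too few for the set test. Eif2s3y, Uty and Zfy1 were detected on 3 knockout arrays and 0 wild-type arrays, and Uty and Zfy1 were at least 1.77-fold and 1.33-fold higher in the knockout. The other probes of these genes (1 of Eif2s3y, 3 of Uty and 1 of Zfy1) and those of Zfy2, Usp9y and Sry were not above background on any array. Of 2 Kdm5d probes, 1 was detected on 1 wild-type array and the other on none. Of 20 chromosomes tested, 0 passed camera, 0 had an unadjusted p under 0.05 (lowest 0.262) and 0 passed with an estimated correlation. Chromosome medians ran from -0.03 to 0.05. The bootstrap interval lay above 0 for chromosomes 7 (0.006 to 0.050), 8 (0.024 to 0.077) and 11 (0.004 to 0.057), and below 0 for the X chromosome (-0.08 to -7.3e-05; 372 genes, median -0.03).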

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

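Probes with no gene name enter none of the comparisons by gene. Of 2527 such probes that passed the detection filter, 786 passed the threshold and 108 of these changed at least 2-fold, 35 higher and 73 lower in the knockout. The probe with the largest change, ILMN_2899599, had a log2 change of 3.06 ± 0.11 (SE), with a mean normalized log2 intensity of 9.50 in the knockout and 6.44 in the wild type. Among probes with no gene name 31.1% passed, against 31.8% of the probes with 1 gene name.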

How the results depend on the processing

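The count of genes past the threshold stayed within 1.5 times of 3745 under every alternative run (2868 with median scaling to 4195 with array weights), and ran from 2735 to 4082 when 1 array was left out. Of the 3745 genes, 71.7% to 98.8% passed again, depending on the alternative. The count changed at least 2-fold fell from 378 to 174 with no background correction and 158 with normexp at an offset of 50, and ran from 363 to 422 when 1 array was left out. The number of lists past the test went from 14 to 0 for camera with an estimated correlation and to 22 with fry, and ran from 12 to 15 when 1 array was left out. No chromosome passed under any alternative run. Trpm7, fitted by its brightest probe without the detection filter, did not pass under any alternative for which it was run (log2 change -0.23 to -0.07 when 1 array was left out). It was not run with detection on all arrays or the mean of probes.

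There was no sign that the replicate numbers pair the samples. Deviations of same-numbered arrays correlated at 0.06, 0.05 and -0.15, and no knockout array correlated best with its own number. With 3 arrays per clone this cannot exclude a pairing, under these or other numbers. With the replicate block 3424 genes passed, 378 of them changed at least 2-fold, 14 lists passed, 0 chromosomes passed, and Trpm7 had a log2 change of -0.16. Leaving out X and Y genes, chosen after the data were seen, gave 3604 genes, 364 changed at least 2-fold, and 15 lists. The array chip is not named in the sources used here, so a chip block was not run.

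Among named genes, signs reversed only for changes that had not passed, and for Actb. Actb gave 0.31 with the mean of probes. Sox2 gave -0.0086 with the mean of probes, and -0.12 to 0.13 when 1 array was left out, below 0 without knockout replicate 3 (-0.12) or wild-type replicate 1 (-0.027). Zfp42 gave 0.028 with median scaling, and -0.071 to 0.026 when 1 array was left out, above 0 without knockout replicate 2 (0.026) or wild-type replicate 2 (0.00051). Mt1 gave -0.064 to 0.16 when 1 array was left out, below 0 without knockout replicate 2 (-0.064) or wild-type replicate 3 (-0.014). Of 146 named genes tested, 134 to 145 kept direction and side of the threshold when 1 array was left out. Apart from the averaging of Actb probes that disagree, the cause was not tested.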

Other observations

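The tests of feeder cells, array scaling, probe families, a changed share of cells, the X chromosome and other splits of the arrays were chosen after the results were seen. The limits for YAP/TEAD targets were written before the values of the tested members were seen. A scan of 320 gene families by symbol stem, also chosen afterwards, gave 6 past camera (Tdpoz, Gng, Hspb, Pramel, Bmp and Col), each with a median below 0, and 0 with an estimated correlation. All 6 tested Gng genes, which encode G protein gamma subunits, fell (median log2 change -0.76), as did 4 of 5 small heat shock genes of the Hspb family (median -0.99).

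The fibroblast and actomyosin lists were lower in the knockout clone (19 of 25 and 20 of 31 members fell), though neither passed with an estimated correlation (adjusted p = 0.0677 and 0.0987). Leftover feeder fibroblasts in the wild-type cultures could not be settled as a cause. Among Col1a1, Col1a2, Col3a1, Postn, Lum and Dcn, abundant in fibroblasts, the largest wild-type excess was 6.91% of the median excess of the 19 members that fell (linear signal 7.72 against 111.6). That excess was of Col1a1, detected on 3 wild-type and 0 knockout arrays, which goes with feeders. Dcn, whose tested probe was above background on all arrays, was higher in the knockout, which goes against them. Probes differ in response and most of these lay at or near background, so the comparison cannot exclude feeders. Array scaling is argued against, since the fibroblast list's median stayed at -0.71 with median scaling. A candidate explanation is a lower YAP/TEAD target programme, which responds to cell tension. Of 15 targets not seen before 7 could be tested, of which 6 fell and 0 rose, with a median of -0.60. Their p-values were not adjusted (camera p = 0.000717, or 0.0253 with an estimated correlation). Unadjusted, the fibroblast and actomyosin lists gave p = 0.00178 and 0.0173 with an estimated correlation, so the targets did not pass where these lists failed. The idea came from seen targets such as Axl and Ccn2. Ccn1 and Ccn2 are also members of the fibroblast list, and feeder cells may express the other targets too. Lower targets thus do not separate a lower programme from leftover feeders. Whether Trpm7, the clone or feeders account for the pattern stays open.

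The 2-cell-like list was lower in the knockout clone (10 of 12 members fell), though it did not pass with an estimated correlation (adjusted p = 0.0987). Probes of 1 gene family reading the same transcripts would not account for it, as the 10 members that fell carry 7 symbol stems and lie on 6 chromosomes. The list was made up of many stems, so this followed once most members fell. Members with the same stem may still share signal. A smaller share of cells in that state would lower its genes alike. Among the 5 members that fell and were still detected on all knockout arrays, linear signal was 14.3% to 37.3% of wild type, a spread of 2.62-fold, between the limits set for and against it. Bulk RNA gives no level per cell, so a smaller share and a lower level per cell cannot be told apart.

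Y-linked genes were at background in the wild-type clone. A second active X chromosome there would lower X-linked genes in the knockout. Their median was -0.030 over 372 genes (bootstrap interval -0.076 to -7.3e-05), which argues against it. Y probes reading X-linked copies is argued against by Eif2s3x, with a log2 change of 0.18 beside 4.92 for Eif2s3y. Xist probes were detected on at most 2 of 6 arrays. A wild-type clone that lost its Y chromosome stays open as a hypothesis. One from an embryo without a Y stays open only if the clone had no second active X chromosome. Either would be a difference between clones other than Trpm7.

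With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3745 genes and the highest of the others 0; for genes changed at least 2-fold the values were 378 and 0 (1 split as large in both cases, the real one included). For lists they were 14 and 14, with 2 splits as large, and for chromosomes 0 and 0, with 10. Each other split leaves 2 arrays of a genotype against 1. It keeps only part of any difference between the clones and adds the rest to the spread within groups. Lower gene counts and smaller medians were therefore built into these splits, and do not show what chance would give. List calls can carry over from the clone difference, so the equal list count does not show it either. The median of the 2-cell-like list was -1.55 in the real split and at most 0.64 in size in the other 9, and that of the fibroblast list -0.76 and 0.30, yet both lists passed camera in 7 of those 9. Of the 14 lists past camera, 13 had their largest median in the real split, the endoderm list narrowly (-0.303 against 0.296). The FGF list did not (-0.17), with 4 of 9 other splits as large.

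Of 5 Actb probes, 3 varied between arrays of the same clone. Probe ILMN_1377923 read 12.3, 10.2 and 12.2 on knockout replicates 1, 2 and 3 and 10.2, 10.3 and 12.2 on wild-type replicates 1, 2 and 3. It and ILMN_2846865 and ILMN_2588055 had the 3 largest spreads within clones among 19123 kept probes. The brightest Actb probe, ILMN_2698799, ran from 13.9 to 14.0 in the knockout and from 14.2 to 14.3 in the wild type.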
